A study of Mus musculus with 13 samples.

How the data were processed

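The series held 13 single-colour Illumina mouse BeadChip arrays on 3 slides, with 45281 probes each. Per the labels, RNA was extracted from flash-frozen brain or tumor with a kit for lipid-rich tissue and labelled with biotin. Groups were taken from the labels: Nestin tumor (3 arrays), Nestin control (3), NG2 tumor (4) and NG2 control (3). The design text states 5 NG2 tumors, and 1 of these was not analysed here. The slide of each array was read from the array identifiers in the deposited table.

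The authors deposited a table of non-normalized intensity values, the average bead signal of each probe on each array, and per the file headers each value is paired with a detection p-value. By its standard definition that p-value sets a probe against the negative control probes of the array. Whether the scanner software had subtracted background from the intensity values is not given in the sources used here. The lowest signal of an array ran from 91.49 in NG2 control 2 to 142.5 in NG2 tumor 1, which argues against a subtraction. The authors also deposited a processed table of 38563 probes, taken here as log2 values because of their range, and the method and reference of that normalization are not given in the sources used here. Each of its 13 columns correlated with its own array (r at least 0.999987 with the values computed here) better than with any other (at most 0.9883), and its column medians ran from 5.286 to 5.306. It served as an alternative only.

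Intensities were corrected and normalized with neqc from limma 3.58.1 in R 4.3.3, which estimates background from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. Probes were kept with a detection p below 0.05 on at least 3 arrays, which left 23904 probes. Genes were named from the platform's probe table: 32093 probes had 1 symbol, 16 had several and were not used, and 13172 were unnamed here. Of the named probes 32035 matched a gene by Entrez number in a RefSeq table of assembly GRCm38.p6, used for names alone, and 0 symbols changed. No genome build came with the arrays, so no coordinates are given. Where a gene had several probes the one with the highest mean signal was used, which gave 11927 genes from 18876 named probes. Probes of 1 gene changed in opposite directions for 60 genes in the Nestin comparison, 95 in the NG2 comparison and 1 in the difference of effects, among 4680 genes with several probes. For arrays the number of samples limits the precision.

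A linear model with 1 mean per group was fitted to all 13 arrays with limma, with residual degrees of freedom of 9 and a prior of 4.66 from empirical Bayes moderation with an intensity trend. All 4 groups shared 1 estimate of the spread. The comparisons were Nestin tumor against Nestin control, NG2 tumor against NG2 control, Nestin tumor against NG2 tumor, Nestin control against NG2 control, and the difference between the 2 tumor effects. The adjusted p-values are Benjamini-Hochberg values over the genes of each comparison, with a threshold of 0.05. A gene counted as not well above background in a group when no probe of it had a detection p below 0.05 on any array there, and its change against a brighter group is given as a lower bound. Values for the difference of effects are fitted values with no such bound, also for genes near background in a group.

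Before the data were examined, 34 lists with 538 entries (511 genes, 387 of them measured) were fixed, together with the comparisons, the alternatives and the rule for the genes named. The lists covered deleted tumor suppressors, Cre driver genes, mitosis, DNA replication, oligodendrocyte progenitors, myelin, astrocytes, neural stem and progenitor cells, neuroblasts, neurons, glutamate and GABA receptors, 3 brain regions, microglia and macrophages, lymphocytes, neutrophils, antigen presentation, interferon response, endothelium, pericytes and smooth muscle, hypoxia, extracellular matrix, 3 human glioblastoma subtypes, p53 targets, MAPK output, immediate early genes, erythrocytes, choroid plexus, ependyma, meninges and fibroblasts, and sex-linked genes. The 29 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. With the estimated correlation the calls that held were the dorsal telencephalon list in the Nestin and NG2 comparisons and the neuroblast and dorsal telencephalon lists between controls. The genes named were the 10 largest rises and 10 largest falls of each comparison among genes past the threshold whose groups did not overlap, the 4 largest changes of each list in a comparison, and Nf1, Nes, Cspg4, Gfap, Olig2, Pdgfra, Sox10, Erbb3, Egfr and Dcx. For a gene named by the rule in 1 comparison, values in others may be given.

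The alternatives were normexp background correction with an offset of 50, no background correction, cyclic loess, scaling to the median, the authors' processed values, no filter on dim probes, a filter at a detection p of 0.01 on every array of a group, the mean of a gene's probes, every probe on its own, no intensity trend, array weights, the replicate number as a block, the letter in the title as a block, the slide as a block, a fit with the compared groups alone, a threshold of 0.01, a threshold of 0.05 with at least a 2-fold change, an estimated correlation and fry for the lists, and leaving out each array. Leaving out slide 3 and a block for sex, read from Xist, were added after seeing the data. The overlaps of comparisons that share arrays were set against 100 simulations with no effect. On simulated data with 200 of 11927 genes changed, the share of changed genes recovered at log2 sizes of 1, 2 and 4 was 26.9%, 92.5% and 95.5% for the Nestin comparison, 35.8%, 86.6% and 98.5% for the NG2 comparison, 34.3%, 88.1% and 100% between tumors, 26.9%, 79.1% and 98.5% between controls, and 11.9%, 64.2% and 92.4% for the difference of effects. The share recovered depends on how many genes change. It does not describe the Nestin and NG2 comparisons, where 5522 and 6041 genes passed. False calls in the simulations were 12 of 155 calls for the Nestin comparison and 9 of 156 for the NG2 comparison. They were 8 of 156 between tumors, 7 of 143 between controls and 4 of 116 for the difference of effects. All arrays of a gene were simulated with the same spread and no slide effect. In the data the median SD of a gene was 0.3 and 0.347 log2 in Nestin and NG2 tumors, against 0.221 and 0.274 in their controls. The simulated shares therefore do not test the shared spread, least of all between tumors. Array medians and detected shares were compared with exact permutation tests.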

Results

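Gene expression was measured in high-grade gliomas of 2 mouse models and in control brain. In both models Cre recombinase, an enzyme that deletes DNA between its target sites, removed tumor suppressor genes. In the Nestin-creERT2 model Cre was driven by sequences of the gene for nestin, an intermediate filament protein of neural stem and progenitor cells. In the NG2-creERTM model it was driven by sequences of the gene for NG2, a surface proteoglycan of oligodendrocyte progenitors and pericytes. The ER forms of Cre are activated by tamoxifen. Total RNA from flash-frozen tissue was hybridised to 13 Illumina mouse arrays: 3 Nestin tumors, 3 Nestin controls, 4 NG2 tumors and 3 NG2 controls. The labels call the tumors independent tumors and the controls biological replicates, so each array was treated as a separate sample. The design text states 5 NG2 tumors, of which 1 was not analysed here. Tumors were taken when the mice showed neurological symptoms, and control brain came from the matching anatomical position, which the labels do not name.

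The arrays carried 45281 probes, and the median raw signal ran from 116.9 to 209.1 across arrays. It was higher in the 7 tumor arrays (189.8 ± 10.35, SD) than in the 6 control arrays (129 ± 9.54, SD), with an exact two-sided permutation p of 0.000583, the smallest that these 1716 splits can give. Tumor arrays were also brighter within each of the 3 slides, at 181 against 132.5, 193.3 against 122.3 and 193.5 against 132.4. The share of probes detected above background was 44.9% in tumors and 45.6% in controls (exact two-sided permutation p = 0.273) and ran from 43.46% to 47.52%. Replicates correlated across genes at 0.937 to 0.961 among Nestin tumors, 0.94 to 0.955 among NG2 tumors, 0.982 to 0.983 among Nestin controls and 0.973 to 0.98 among NG2 controls. The median SD of a gene was 0.3 log2 in Nestin tumors and 0.347 in NG2 tumors, against 0.221 and 0.274 in their controls. The number of arrays limits the precision of every value. The first principal component held 67.2% of the variance and parted all tumors from all controls, and the second held 8.26% and parted Nestin tumors from NG2 tumors.

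**Figure D1:**
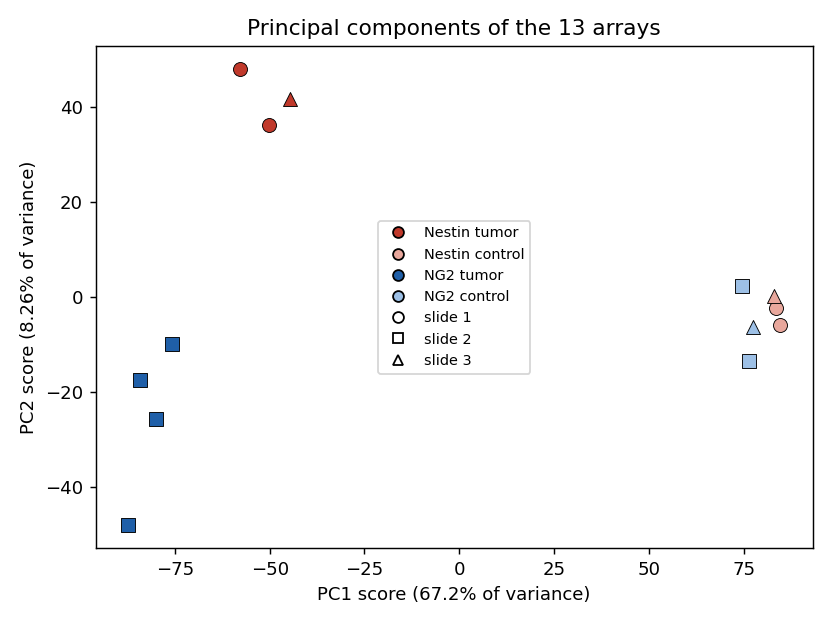
Scores of the 13 arrays on the first 2 principal components of the 11927 tested genes (x axis, PC1, 67.2% of variance; y axis, PC2, 8.26%); colour gives the group and marker shape the slide. Tumors lie at -87.3 to -44.7 on PC1 and controls at 74.7 to 84.6; Nestin tumors lie at 36.3 to 48.1 on PC2 and NG2 tumors at -48.1 to -10.0.

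Slide and group overlapped in part. Slide 1 held Nestin tumors 1 and 2 with Nestin controls 1 and 2, slide 2 held all 4 NG2 tumors with NG2 controls 1 and 2, and slide 3 held Nestin tumor 3, Nestin control 3 and NG2 control 3. Tumor and control could therefore be compared within slides, while no slide held tumors of both models. Differences are given as log2 values ± the standard error of the limma fit with 3 arrays per group, 4 for NG2 tumors, and gene list tests are camera tests. Where a gene was well above background on no array of 1 of the groups, the change is given as "at least N-fold": the brighter group's mean against the dim group's mean raised to the lowest level detected on each array.

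The labels do not name the deleted genes. Nf1, a negative regulator of Ras placed on the list of deleted tumor suppressors from general knowledge of mouse glioma models, was the only measured member of that list. Its mean level was 4.91 log2 in Nestin tumors, above background on 0 of 3 arrays, and 6.56 in Nestin controls, above background on all 3. In NG2 tumors it was 5.55, above background on 2 of 4 arrays, against 6.58 in NG2 controls. On single arrays it ran from 4.87 to 4.97 in Nestin tumors, 6.2 to 6.83 in Nestin controls, 4.98 to 6.06 in NG2 tumors and 5.81 to 7.69 in NG2 controls. Nf1 fell at least 2.29-fold in Nestin tumors (adjusted p = 0.00459) and fell by 1.03 ± 0.38 log2 in NG2 tumors (adjusted p = 0.038). The NG2 value did not pass without NG2 tumor 3 (-0.94), NG2 tumor 4 (-0.83) or NG2 control 3 (-0.47). The position of its probe relative to any deleted part is unknown, so the value settles nothing about the deletion. The genes whose sequences drove Cre rose in the tumors of both models. Nes rose at least 14.0-fold in Nestin tumors and by 3.95 ± 0.32 in NG2 tumors (adjusted p = 6.59e-07 and 3.12e-07), with a difference between the 2 tumor groups of -0.02 ± 0.32 (adjusted p = 0.975). Cspg4, which encodes NG2, rose by 2.92 ± 0.43 in NG2 tumors (adjusted p = 7.78e-05) and by 1.55 ± 0.46 in Nestin tumors (adjusted p = 0.0139), where it did not pass without Nestin tumor 1 (1.03). Cspg4 differed between the tumor groups by -1.05 ± 0.43 (adjusted p = 0.145), which passed without Nestin tumor 1 (-1.56).

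The comparison of Nestin tumors with Nestin controls asked which genes separated the tumors from brain of the corresponding position. Genes of cell division were among the largest rises. Pbk, a mitotic kinase, was 96.0-fold higher (6.58 ± 0.24, adjusted p = 1.03e-09). Prc1, a protein of the central spindle, rose by 6.06 ± 0.31, and Cdk1, the kinase that starts mitosis, rose at least 41.0-fold. Uhrf1, which keeps DNA methylation through replication, rose by 5.87 ± 0.30, and Pclaf, a partner of the replication clamp, at least 35.8-fold. The patterning gene Hoxa7, not a gene of cell division, rose at least 41.7-fold. All 15 measured mitosis genes rose (mean 4.24, adjusted p = 6.77e-14, and adjusted p = 0.0537 with an estimated correlation), among them Birc5 at 5.25 ± 0.30 and Nusap1 at 5.13 ± 0.26. Of 20 DNA replication genes 18 rose, 19 when adjusted over the list alone (mean 2.88, adjusted p = 3.7e-12, and adjusted p = 0.0649 with an estimated correlation). Tyms, which makes thymidylate, rose by 4.78 ± 0.25, and Mcm6, a subunit of the replicative helicase, by 4.20 ± 0.26. For each list given without a count adjusted over the list alone, that count was the same as the count over all genes.

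Neuronal genes had the largest falls in Nestin tumors. Lamp5, a membrane protein of cortical neurons, fell by 5.96 ± 0.53 (adjusted p = 1.32e-06), Slc17a7, the vesicular glutamate transporter of cortical neurons, was 42.7-fold lower (-5.42 ± 0.69), and Camk2a, a synaptic kinase, fell by 5.40 ± 0.35. Of 16 neuron genes 15 fell and 0 rose (mean -3.15, adjusted p = 1.32e-08, and adjusted p = 0.104 with an estimated correlation). All 9 genes of the dorsal telencephalon region fell, and this was the only list of the comparison whose call held with an estimated correlation (mean -3.33, adjusted p = 5.89e-06, and adjusted p = 0.018 with an estimated correlation). Tbr1 and Fezf2, transcription factors of deep-layer cortical neurons, fell by 5.41 ± 0.23 (Tbr1) and fell by 4.10 ± 0.42 (Fezf2). Of 12 glutamate and GABA receptor genes 9 fell, with 1 rise and 9 falls adjusted over the list alone (mean -1.61, adjusted p = 0.00154, and adjusted p = 0.103 with an estimated correlation). Gabrd, a subunit of extrasynaptic GABA receptors, fell by 4.75 ± 0.28. Of 12 striatum region genes 7 fell, among them the dopamine receptor gene Drd2 at -2.37 ± 0.58 (mean -1.75, adjusted p = 0.00484, and adjusted p = 0.495 with an estimated correlation). Of 15 myelin genes 12 fell and 0 rose (mean -2.23, adjusted p = 3.06e-05, and adjusted p = 0.151 with an estimated correlation). Mog, a protein of the outer myelin surface, fell by 4.15 ± 0.53 and Cnp, an oligodendrocyte enzyme, fell by 3.25 ± 0.43.

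Many neural stem cell genes and some oligodendrocyte progenitor genes rose in Nestin tumors. Egfr, a growth factor receptor, was 8.11-fold higher (3.02 ± 0.61, adjusted p = 0.00109). Vim, a filament protein of immature glia, rose by 3.89 ± 0.36 and Tnc, a matrix glycoprotein of germinal zones, by 4.37 ± 0.75. Of 16 neural stem and progenitor genes 11 rose and 0 fell (mean 2.06, adjusted p = 3.06e-05, and adjusted p = 0.0537 with an estimated correlation). Of 20 oligodendrocyte progenitor genes 10 rose and 1 fell (mean 0.95, adjusted p = 0.00919, and adjusted p = 0.484 with an estimated correlation), and the list did not pass without Nestin tumor 1 (mean 0.68). Olig2, a transcription factor of the lineage, rose by 2.36 ± 0.35 and Pdgfra, the receptor that drives progenitor division, by 1.70 ± 0.46 (adjusted p = 0.000118 and 0.0079). Sox10, another factor of the lineage, differed by -0.16 ± 0.47 (adjusted p = 0.808), and Erbb3, a neuregulin receptor, was not well above background in either group. Gfap, the filament protein of astrocytes, rose by 2.19 ± 0.53 (adjusted p = 0.004), while Aldh1l1, an astrocyte enzyme, fell by 2.28 ± 0.32. The astrocyte list had 2 rises and 2 falls, 2 and 1 adjusted over the list alone, and did not pass (mean 0.07, median -0.06, adjusted p = 0.96). The neuroblast list did not pass either, with 3 rises and 3 falls, 4 and 3 adjusted over the list alone (mean 0.42, median -0.25, or -0.11 with dim genes at their bounds, adjusted p = 0.947). Sox11, a factor of newborn neurons, rose by 3.58 ± 0.42, and Dcx, a microtubule protein of migrating neurons, differed by 1.81 ± 0.74 (adjusted p = 0.0586). Dcx passed without Nestin tumor 2 (2.20), NG2 tumor 2 or NG2 tumor 4 (1.81 for both). NG2 arrays enter the Nestin comparison through the shared spread, the joint normalization and the filter on dim probes.

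The 3 lists of human glioblastoma subtype genes and the regional lists gave mixed counts in Nestin tumors. Of 19 mesenchymal subtype genes 14 rose and 0 fell, 15 and 1 adjusted over the list alone (mean 2.03, adjusted p = 2.6e-05, and adjusted p = 0.104 with an estimated correlation). The galectin gene Lgals3 rose by 4.90 ± 0.39 and the hyaluronan receptor gene Cd44 by 4.52 ± 0.37. Of 14 proneural subtype genes 7 rose, 8 adjusted over the list alone (mean 1.45, adjusted p = 0.00443, and adjusted p = 0.104 with an estimated correlation). Pdgfra, Olig2, Sox10, Erbb3, Gpr17 and other genes stand on both the proneural and the oligodendrocyte progenitor list, so these are not separate results. The classical subtype list did not pass (mean 0.79, adjusted p = 0.17); 4 of its 13 genes rose and 2 fell, 6 and 2 adjusted over the list alone. The diencephalon and brainstem region list rose, with 10 rises and 1 fall among 14 genes (mean 2.26, adjusted p = 0.000275, and adjusted p = 0.104 with an estimated correlation). Its largest rises were of factors that pattern the embryonic hindbrain, midbrain and thalamus: En1 rose at least 33.4-fold, Hoxa5 26.8-fold, Irx2 22.0-fold and Gbx2 17-fold. Slc17a6, the vesicular glutamate transporter of neurons in these regions, fell by 4.37 ± 0.49.

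Many immune and matrix genes rose in Nestin tumors. Of 13 interferon response genes 12 rose (mean 2.75, adjusted p = 0.000136, and adjusted p = 0.477 with an estimated correlation). Usp18, a regulator of interferon signalling, rose by 4.87 ± 0.59 and Oasl2 by 4.39 ± 0.53. Of 15 antigen presentation genes 12 rose (mean 1.81, adjusted p = 0.000275, and adjusted p = 0.464 with an estimated correlation), with H2-Ab1, a class II chain, at 2.95 ± 0.44. Of 16 microglia and macrophage genes 10 rose (mean 1.46, adjusted p = 0.00443, and adjusted p = 0.502 with an estimated correlation). Gpnmb rose by 3.66 ± 0.60 and the lysozyme gene Lyz2 by 3.26 ± 0.46. Without Nestin tumor 2 the list did not pass (mean 0.97). Of 16 extracellular matrix genes 9 rose (mean 1.68, adjusted p = 0.00484, and adjusted p = 0.484 with an estimated correlation), among them Timp1, a metalloproteinase inhibitor, at least 22.4-fold. Of 15 MAPK output genes 8 rose and 1 fell (mean 1.06, adjusted p = 0.0174, and adjusted p = 0.488 with an estimated correlation). Ccnd1, the cyclin of early G1, rose by 3.02 ± 0.30, and the list did not pass without Nestin tumor 1 (mean 0.86). Single genes with large rises were the chemokine gene Cxcl10, at least 32.7-fold, the iron-binding lipocalin gene Lcn2 at 5.58 ± 1.03 and Igfbp3, which binds insulin-like growth factors, at 5.74 ± 0.42. The endothelium, pericyte and smooth muscle, hypoxia, immediate early, p53 target, neutrophil, choroid plexus, ependyma, and meninges and fibroblast lists did not pass, with adjusted p from 0.563 to 0.947. Within them Angpt2, a destabilizer of vessels, rose by 3.98 ± 0.44 and Angptl4, a hypoxia gene, by 3.66 ± 0.52. The endothelium list had a mean of 0.08 and a median of -0.13, the p53 target list 0.33 and -0.07, and the pericyte list a mean of 0.11 with a test in the opposite direction.

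In all, 5522 of 11927 genes passed in Nestin tumors, 2905 higher and 2617 lower, and 3987 of them changed at least 2-fold. A block for the slide left 5242, 5186 of them shared with that count. Within slide 1, with 2 tumors and 2 controls, 3998 passed. Slide 3 held 1 tumor and 1 control, which give no spread of their own, so only sizes are given for it. The mitosis list had a mean of 4.16 within slide 1 and 4.41 within slide 3, the neuron list -3.46 and -2.54, and the oligodendrocyte progenitor list 1.19 and 0.46. Of the genes named, those above background on only some arrays of a group were Pbk and Birc5 (2 of 3 controls), Uhrf1, Nusap1 and Lcn2 (1 of 3 controls), Slc17a7, Tbr1, Gabrd and Slc17a6 (2 of 3 tumors), and Drd2 and Cd6 (1 of 3 tumors). With each array scaled to its median, the median change of all genes was 0.451 log2 in Nestin tumors, against 0.06 without this, and 0.467 in NG2 tumors, against 0.09. This scaling raised the share of higher calls from 52.6% to 72.9% and from 52.4% to 71.8%.

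NG2 tumors were set against NG2 controls in the same way, and cell division genes had the largest rises. Pbk rose by 7.07 ± 0.22 (adjusted p = 1.86e-10), and Top2a, the topoisomerase of dividing cells, was 107-fold higher (6.74 ± 0.35). Kif2c, a mitotic kinesin, rose at least 44.6-fold, Cdk1 at least 56.7-fold, and Cdc20, an activator of the anaphase-promoting complex, rose by 5.92 ± 0.27. All 15 mitosis genes rose (mean 4.82, adjusted p = 1.09e-13, and adjusted p = 0.0513 with an estimated correlation). Of 20 DNA replication genes 19 rose, 20 adjusted over the list alone (mean 3.38, adjusted p = 3.12e-13, and adjusted p = 0.0513 with an estimated correlation), with Uhrf1 at 6.33 ± 0.28 and Tk1, a thymidine kinase, at least 23.2-fold higher.

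The largest falls in NG2 tumors were again neuronal. Ddn, a dendritic protein gene, was 209-fold lower (-7.71 ± 0.45, adjusted p = 1.31e-08). Gad2 and Slc32a1, which make and load the transmitter GABA, differed by -6.98 ± 0.55 and -6.63 ± 0.61. Rbfox3, which encodes the neuronal marker NeuN, fell by 6.25 ± 0.35, and Lamp5 fell by 7.20 ± 0.50. Of 16 neuron genes 15 fell and 0 rose (mean -4.75, adjusted p = 3.35e-11, and adjusted p = 0.0725 with an estimated correlation). All 9 dorsal telencephalon genes fell, the only list here whose call held with an estimated correlation (mean -3.22, adjusted p = 2.85e-05, and adjusted p = 0.0303 with an estimated correlation). Bcl11b fell by 4.83 ± 0.42 and Tbr1 was at least 15.1-fold lower. Of 12 receptor genes 9 fell, 10 adjusted over the list alone (mean -2.72, adjusted p = 2.72e-05, and adjusted p = 0.0513 with an estimated correlation). The AMPA receptor gene Gria1 fell by 6.12 ± 0.40. Of 12 striatum region genes 10 fell (mean -2.17, adjusted p = 0.00264, and adjusted p = 0.418 with an estimated correlation). The neuroblast list fell, with 8 falls and 2 rises among 12 genes (mean -1.97, adjusted p = 0.00728, and adjusted p = 0.364 with an estimated correlation). The fall rests on NG2 controls, which had the highest level of this list (9.53 log2, against 7.84 in Nestin controls and 7.56 in NG2 tumors). In a test chosen after the results were seen, 10 of 12 olfactory bulb genes that stood on no other list fell with it (mean -2.36), so the fall was not told apart from a difference in bulb tissue between the NG2 pieces. Dlx1 and Dlx2, factors of GABAergic precursors, fell at -5.96 ± 0.72 and -3.08 ± 0.33, and Gad1, the other GABA-producing enzyme, fell by 5.16 ± 0.32. Dcx differed by -1.76 ± 0.69 (adjusted p = 0.0473) and did not pass without Nestin tumor 3, NG2 tumor 1, NG2 tumor 4 or any 1 of the 6 controls (-1.93 to -0.97). Of 15 astrocyte genes 10 fell and 1 rose (mean -1.35, adjusted p = 0.00942, and adjusted p = 0.418 with an estimated correlation). Gjb6 and Gja1, which encode gap junction proteins of astrocytes, changed by -4.78 ± 0.59 and -2.54 ± 0.61. Gfap differed by 0.40 ± 0.50 (adjusted p = 0.527).

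Oligodendrocyte progenitor genes rose in NG2 tumors, 15 of 20 with 0 falls (mean 1.75, adjusted p = 3.39e-05, and adjusted p = 0.186 with an estimated correlation). Sox10 rose by 3.02 ± 0.44 (adjusted p = 6.63e-05), Olig2 by 3.13 ± 0.33, Pdgfra by 2.69 ± 0.43 and Gpr17, a receptor of committed progenitors, by 3.6 ± 0.69. Vcan, a proteoglycan of progenitors, rose at least 10.6-fold and Erbb3 at least 1.97-fold. Egfr differed by -0.90 ± 0.57 and did not pass (adjusted p = 0.204). Of 16 stem and progenitor genes 10 rose (mean 1.59, adjusted p = 0.00119, and adjusted p = 0.0725 with an estimated correlation). Tnc rose by 5.36 ± 0.70 and Sox2, a stem cell factor, by 2.46 ± 0.41. Of 14 proneural genes, some of which are also on the oligodendrocyte progenitor list, 10 rose and 1 fell (mean 1.74, adjusted p = 0.00103, and adjusted p = 0.0725 with an estimated correlation). Of 19 mesenchymal genes 14 rose and 1 fell, 15 and 1 adjusted over the list alone (mean 2.32, adjusted p = 3.97e-05, and adjusted p = 0.133 with an estimated correlation). The myelin list did not pass (mean -1.23, adjusted p = 0.0932). Of 15 genes 7 fell, with Mobp at -4.43 ± 0.49 and Mog at -3.28 ± 0.50, and 3 rose, among them Ugt8a, which makes the myelin lipid galactosylceramide, at 1.34 ± 0.26. The myelin list passed without NG2 tumor 3 (mean -1.40). Of 14 diencephalon and brainstem genes 9 rose and 1 fell (mean 1.93, adjusted p = 0.00245, and adjusted p = 0.175 with an estimated correlation). As in Nestin tumors the members were patterning factors, with Hoxa5 at least 22.8-fold, Irx2 22.6-fold and En1 19-fold higher, while Slc17a6 fell by 5.61 ± 0.46.

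Among immune and matrix lists in NG2 tumors, interferon response rose for 10 of 13 genes (mean 2.42, adjusted p = 0.000474, and adjusted p = 0.418 with an estimated correlation), with Usp18 at 4.31 ± 0.55. Antigen presentation rose for 11 of 15 (mean 1.79, adjusted p = 0.000474, and adjusted p = 0.391 with an estimated correlation), with the immunoproteasome gene Psmb8 at 3.01 ± 0.42. Extracellular matrix rose for 10 of 16, 12 adjusted over the list alone (mean 1.99, adjusted p = 0.00103, and adjusted p = 0.391 with an estimated correlation), with Timp1 at 5.91 ± 0.79. MAPK output rose for 10 of 15 with 1 fall (mean 1.33, adjusted p = 0.00547, and adjusted p = 0.391 with an estimated correlation), with Ier3 at 3.40 ± 0.32 and Etv4, a target of the pathway, at 3.21 ± 0.31. The microglia and macrophage list did not pass, with 7 rises and 1 fall among 16 genes (mean 0.83, adjusted p = 0.11). The hypoxia list did not pass (mean 0.70, adjusted p = 0.147) but passed without NG2 tumor 2 (mean 0.94). The endothelium list did not pass (7 rises and 3 falls, adjusted p = 0.247), though Angpt2 rose by 5.30 ± 0.41. The pericyte, classical subtype, p53 target, immediate early, neutrophil, choroid plexus, ependyma, and meninges lists did not pass either, with adjusted p from 0.131 to 0.901. The p53 target list had a mean of 0.22 and a median of -0.03. The lymphocyte, erythrocyte and sex-linked lists had 4 measured genes each and were not tested as lists. Of the lymphocyte genes Cd6, a T cell surface receptor gene, fell by 3.72 ± 0.23 in Nestin tumors and was not well above background in NG2 tumors or controls, and the chemokine gene Ccl5 rose at least 6.36-fold in Nestin tumors (adjusted p = 0.0024). Ccl5 differed by 1.80 ± 0.73 in NG2 tumors (adjusted p = 0.0535) and passed there without Nestin tumor 1 or 2 (1.79 for both) or NG2 tumor 4 (2.42). Cd79b and Cd3e passed in no comparison. Of the erythrocyte genes 1 passed, the globin gene Hba-a1 in NG2 tumors (-2.24 ± 0.89, adjusted p = 0.0492). It did not pass without NG2 tumor 2, 3 or 4 or any 1 of the 6 controls (-2.48 to -1.94), and in Nestin tumors it passed only without Nestin tumor 1 (-2.11, against -0.65). No sex-linked gene passed in any comparison.

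NG2 tumors had 6041 genes past the threshold, 3166 higher and 2875 lower, and 4204 of them changed at least 2-fold. The slide block left 4948, of which 4877 were shared. Within slide 2, which held all 4 tumors and 2 controls, 4721 passed. Within slide 2 the mitosis list had a mean of 4.81, the neuron list -4.72, the oligodendrocyte progenitor list 1.75 and the astrocyte list -1.33. Above background on only some arrays of a group were Pbk, Uhrf1 and Timp1 (2 of 3 controls), Nes, Top2a and Ccl5 (1 of 3 controls), Gad2, Slc32a1, Dlx1, Gjb6, Slc17a6 and Ccl5 (3 of 4 tumors), Ddn, Lamp5 and Nf1 (2 of 4 tumors), and Dlx2 (1 of 4 tumors). Leaving out 1 array at a time gave 5075 to 6187 genes here and 4622 to 5679 in Nestin tumors.

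**Figure D2:**
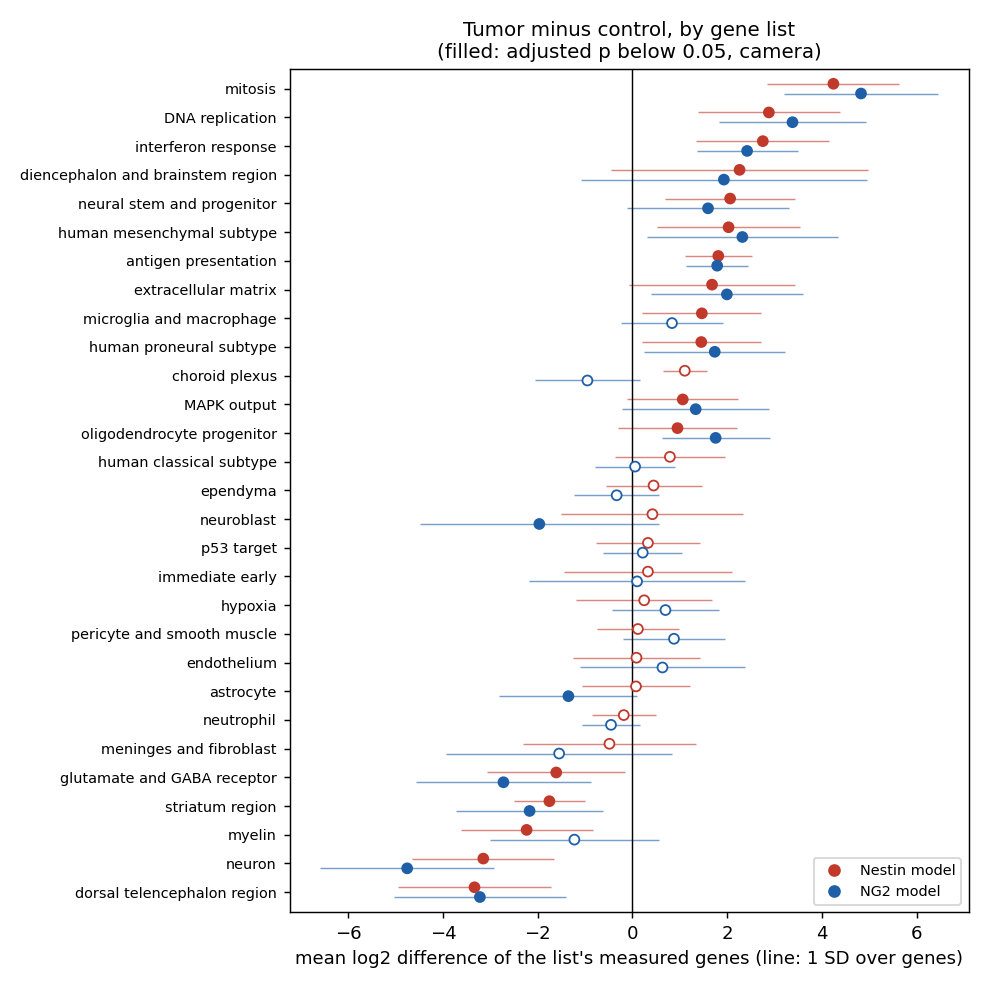
Mean log2 difference between tumor and control (x axis) of the measured genes of each of the 29 tested lists (y axis), for the Nestin model (red) and the NG2 model (blue); lines give 1 SD over the genes of a list, and filled points passed camera at an adjusted p below 0.05. Mitosis genes had the highest means in both models (4.24 and 4.82), and the means of the astrocyte list (0.07 and -1.35) and the neuroblast list (0.42 and -1.97) lay farther apart.

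The tumor effects of the 2 models were compared across genes, which are not independent replicates. They correlated with Pearson's r 0.824 and Spearman's rho 0.8 over 11927 genes, and the 2 effects share no arrays. Of 4170 genes that passed in both models 4138 (99.2%) changed in the same direction, and 32 in opposite directions. Shared rises numbered 2166 against 771.1 for independent lists, and shared falls 1972 against 630.8. Both effects use the same estimate of the spread of a gene, the same normalization and the same filter. The counts for independent lists are therefore only a reference. A different size of effect between the models was found for 186 of the genes that passed in both.

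Nestin tumors were then compared directly with NG2 tumors. Egfr, most genes of the neuron list and some astrocyte genes were higher in Nestin tumors. Col26a1, a collagen gene, was 30.8-fold higher (4.95 ± 0.35, adjusted p = 1.92e-05) and Egfr 15.1-fold higher (3.92 ± 0.57, adjusted p = 0.0016). Gjb6 and Slc39a12, a zinc transporter gene of astrocytes, were higher by 4.41 ± 0.59 and 3.63 ± 0.69, and the neuronal genes Gria1 and Rbfox3 by 4.33 ± 0.40 and 3.92 ± 0.35. Higher in NG2 tumors was Dhh, a hedgehog ligand of Schwann cells, which differed by -4.89 ± 0.76 (adjusted p = 0.00233). The pigment genes Dct and Pmel followed at -4.53 ± 0.79 and -4.34 ± 0.68, the adhesion gene Mcam at -3.65 ± 0.40 and the transcription factor gene Gata6 at -3.64 ± 0.65. A few oligodendrocyte lineage genes were also higher in NG2 tumors, with Sox10 at -2.47 ± 0.44 (adjusted p = 0.00436), Gpr17 at -2.86 ± 0.69 (-1.57 without Nestin tumor 3) and Erbb3, at least 1.92-fold higher. None of these genes passed with the slide as a block. Egfr then differed by 3.27 (adjusted p = 0.528), Sox10 by -3.18 (0.316), Gjb6 by 3.89 (0.471) and Rbfox3 by 4.71 (0.151). Olig2 differed by -0.04 ± 0.33 (adjusted p = 0.957), Pdgfra by -1.02 ± 0.43 (0.153), Gfap by 1.35 ± 0.50 (0.108) and Dcx by 1.90 ± 0.69 (0.105) and none of the 4 passed, nor did Nf1 (adjusted p = 0.321). Gfap passed without NG2 tumor 1 (1.86), Pdgfra without Nestin tumor 1 (-1.53) and Dcx without NG2 tumor 2 (2.47).

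**Figure D3:**
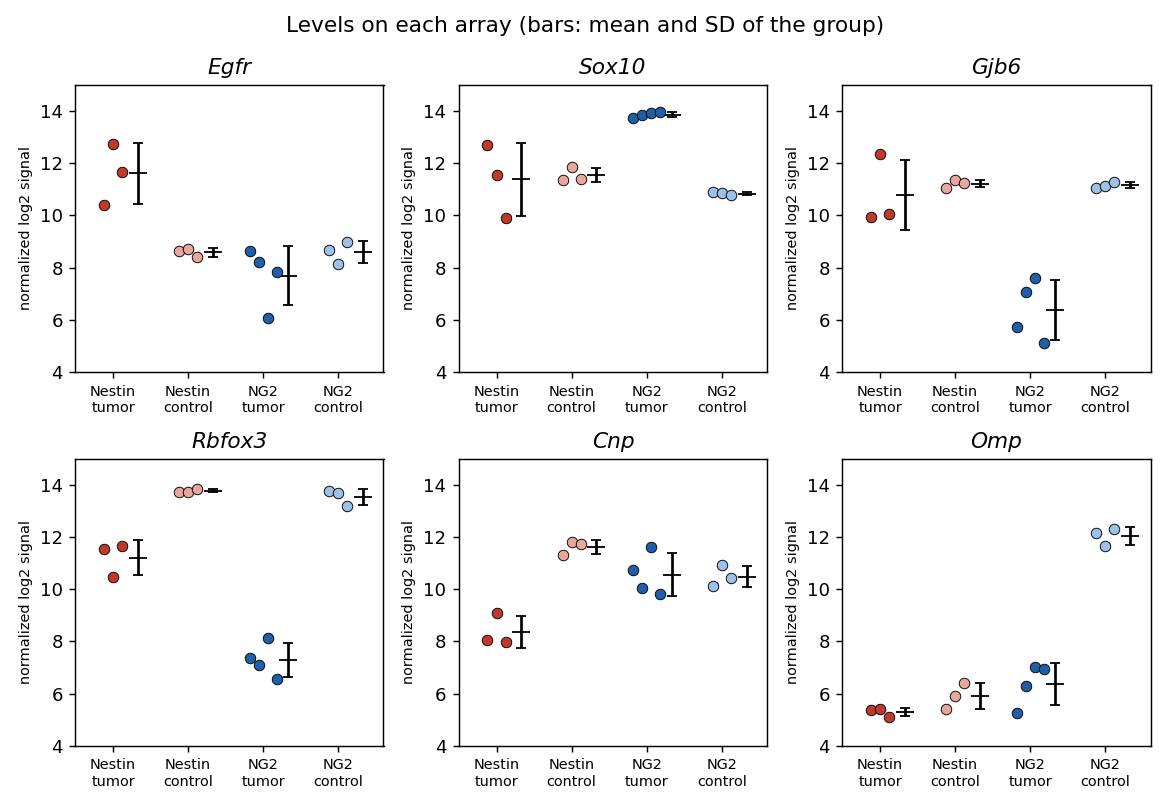
Normalized log2 signal (y axis) of 6 genes on each array (points, grouped by model and tissue on the x axis), with the mean and SD of each group (bars). Egfr averaged 11.61 in Nestin tumors and 7.69 in NG2 tumors, Sox10 11.38 and 13.86, and Omp 12.03 in NG2 controls and 5.90 in Nestin controls.

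By list, 11 of 16 neuron genes were higher in Nestin tumors and 0 lower, 12 adjusted over the list alone (mean 1.79, adjusted p = 4.39e-11, and adjusted p = 0.168 with an estimated correlation). Astrocyte genes were higher for 6 of 15 and lower for 1, 7 and 1 adjusted over the list alone (mean 1.27, adjusted p = 0.000174, and adjusted p = 0.329 with an estimated correlation). Glutamate and GABA receptors (mean 0.97), dorsal telencephalon (mean 0.80) and ependyma (mean 1.17, and 1.85 without Nestin tumor 1) were also higher, with 3 of 12, 2 of 9 and 3 of 10 genes passing and 5 of each adjusted over the list alone. Their tests gave adjusted p = 0.00291, 0.00755 and 0.00345, and adjusted p = 0.168, 0.168 and 0.329 with an estimated correlation. Oligodendrocyte progenitor genes were lower in Nestin tumors for 4 of 20 genes (mean -0.73, adjusted p = 0.00281, and adjusted p = 0.402 with an estimated correlation; mean -0.47 without Nestin tumor 3). Mitosis was lower for 2 of 15 genes, 3 adjusted over the list alone, with Aurkb at -1.17 ± 0.26 (mean -0.48, adjusted p = 0.00281, and adjusted p = 0.402 with an estimated correlation). DNA replication was lower for 2 of 20 genes, with the cyclin gene Ccne2 at -1.27 ± 0.24 (mean -0.39, adjusted p = 0.00291, and adjusted p = 0.407 with an estimated correlation). Endothelium was lower for 4 of 16 genes, 6 adjusted over the list alone (mean -0.62, adjusted p = 0.00399, and adjusted p = 0.329 with an estimated correlation), among them Angpt2 at -1.95 ± 0.41 and Vwf, a clotting factor of endothelium, at -1.56 ± 0.33. The pericyte list was lower for 1 of 9 genes (mean -0.64, adjusted p = 0.0131, and adjusted p = 0.329 with an estimated correlation). The myelin list did not pass (mean -0.03, adjusted p = 0.596), with Hapln2, a link protein of nodes, at least 3.36-fold higher in Nestin tumors and Cnp lower at -2.18 ± 0.40. Its counts were 2 and 3, and 4 and 4 adjusted over the list alone. With the slide as a block the neuron (mean 2.04), dorsal telencephalon, oligodendrocyte progenitor (mean -1.01), astrocyte (mean 1.04), mitosis and DNA replication lists passed again, and the receptor, ependyma, endothelium, pericyte, microglia, matrix, hypoxia and classical lists did not. The proneural (mean -0.74, adjusted p = 0.0308), choroid plexus (mean 2.38, adjusted p = 0.0455) and immediate early lists (mean 0.82, adjusted p = 0.0455) passed with the block and not without it. The choroid plexus value rests on Nestin tumor 3, with a list level of 10.53 log2 against 5.56 and 4.95 in the other Nestin tumors. Leaving that array out, with no block, gave a mean of -0.80 for the choroid plexus list between tumors.

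Further lists of the direct tumor comparison changed their call when 1 array was left out. The classical subtype list passed as higher in Nestin tumors, with 3 of 13 genes, 4 adjusted over the list alone (mean 0.73, adjusted p = 0.0137, and adjusted p = 0.329 with an estimated correlation), but not without Nestin tumor 2 (mean 0.55) or NG2 tumor 3 (0.58). The microglia list passed with 1 of 16 genes higher (mean 0.53, adjusted p = 0.0246, and adjusted p = 0.614 with an estimated correlation), but not without Nestin tumor 2 (0.04, with the test in the opposite direction), NG2 tumor 2 (0.39) or NG2 tumor 4 (0.46). Its mean was 0.87 without Nestin tumor 1. The matrix list passed as lower with 2 of 16 genes (mean -0.64, adjusted p = 0.0246, and adjusted p = 0.607 with an estimated correlation), but not without Nestin tumor 1 (-0.28), NG2 tumor 3 (-0.44) or NG2 tumor 4 (-0.47). The hypoxia list passed as lower with 1 of 15 genes (mean -0.50, adjusted p = 0.0246, and adjusted p = 0.614 with an estimated correlation), but not without Nestin tumor 1 (-0.37), Nestin tumor 2 (-0.38), NG2 tumor 1 (-0.24) or NG2 tumor 4 (-0.37). Some lists did not pass with all arrays but did with 1 left out. The neuroblast list passed without Nestin tumor 2, NG2 tumor 1, NG2 tumor 2 or Nestin control 3 (means 0.79 to 0.90, against 0.70), and the antigen presentation list without Nestin tumor 2 (-0.73) or NG2 tumor 4 (-0.62). The MAPK output list passed without Nestin tumor 1 (-0.54) or NG2 tumor 1 (-0.48). The proneural list passed without Nestin tumor 1 (-0.65), the mesenchymal list without Nestin tumor 3 (-0.56) and the choroid plexus list without Nestin tumor 2 (2.13). With all arrays the 15 lists that did not pass had adjusted p from 0.0649 to 0.959. The meninges list had a mean of -0.05 and a median of 0.34.

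Above background on only some arrays of a group were Col26a1 (2 of 4 NG2 tumors), Gjb6 (3 of 4 NG2 tumors), Pmel and Gata6 (2 of 3 Nestin tumors), and Dhh and Dct (1 of 3 Nestin tumors). Between the tumor groups 1072 of 11927 genes passed, 660 higher and 412 lower in Nestin tumors, and 663 passed without Nestin tumor 3. Limma called 0 genes with the slide as a block, and 1015 had an unadjusted p below 0.05. The median standard error rose from 0.262 to 0.543, and every called gene kept its sign. With only the 7 tumor arrays in the fit 167 genes passed, 166 of them shared and 79% of them higher in Nestin tumors.

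Nestin controls were compared with NG2 controls to see how far the 2 sets of normal tissue differed. Several genes known from the olfactory bulb were lower in Nestin controls. Omp, a protein of olfactory sensory neurons whose axons end in the bulb, was 70.3-fold lower (-6.13 ± 0.41, adjusted p = 6.35e-07), and Th, which makes dopamine in neurons such as the periglomerular cells of the bulb, fell by 5.38 ± 0.23. Scgn, a calcium-binding protein, was lower by 5.12 ± 0.20 log2, and S100a5 and Doc2g were at least 43.7-fold and 43.8-fold lower. Of 12 neuroblast genes 5 were lower, 10 adjusted over the list alone (mean -1.69, adjusted p = 4.33e-12, and adjusted p = 0.0342 with an estimated correlation). Sp8, Dlx2 and Sp9, factors of interneurons that migrate to the bulb, differed by -3.32 ± 0.22, -2.37 ± 0.35 and -2.32 ± 0.18. Cortical genes were higher in Nestin controls, Fezf2 by 2.43 ± 0.42 and Tbr1 by 1.58 ± 0.23. Here 2 of 9 dorsal telencephalon genes passed, 5 adjusted over the list alone (mean 0.91, adjusted p = 0.000254, and adjusted p = 0.0342 with an estimated correlation). Myelin genes were higher for 4 of 15, 8 adjusted over the list alone, with Hapln2 at 1.15 ± 0.28 and Ugt8a at 1.14 ± 0.28 (mean 0.97, adjusted p = 1.31e-06, and adjusted p = 0.251 with an estimated correlation). Cd6 was at least 10.2-fold higher in Nestin controls, and the T cell receptor segment Trbv13-2 by 4.26 ± 0.56. The meninges list was lower with 0 single genes past the threshold, adjusted over the list alone too (mean -1.11, adjusted p = 0.00129, and adjusted p = 0.562 with an estimated correlation), and did not pass with the slide as a block. Nf1, Egfr, Sox10 and Cspg4 differed by -0.02, 0.00, 0.71 and 0.32, and none passed (adjusted p = 0.613 to 0.999). The other 25 lists had adjusted p from 0.443 to 0.984.

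In all 419 genes passed between the control groups, 206 higher and 213 lower in Nestin controls. The slide block left 87, 83 of them shared. Slide 3 held 1 control of each model, which give no spread of their own, so only sizes are given. Within slide 3 the difference was -5.91 for Omp, -5.11 for Th and 2.57 for Fezf2, and the list mean was -1.84 for neuroblast, 1.15 for myelin and 1.14 for dorsal telencephalon. Th and Sp9 were above background on 2 of 3 Nestin controls. The count was 246, 234 and 212 without Nestin control 1, 2 or 3, and 245, 263 and 189 without NG2 control 1, 2 or 3. With only the 6 control arrays in the fit it was 952.

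The last comparison took each model's own controls into account and tested whether the tumor effect differed between the models, as the Nestin effect minus the NG2 effect. Some of its largest values belonged to genes known from the olfactory bulb that were higher in NG2 controls than in Nestin controls. No bulb list was fixed beforehand. Of 12 other bulb genes, chosen after the results were seen, 7 had a higher Nestin effect and 0 a lower one. Calb2, a calcium-binding protein of bulb interneurons, differed by 7.15 ± 0.61 (adjusted p = 1.73e-05), Doc2g by 5.36 ± 0.31, Th by 5.32 ± 0.31 and Omp by 5.06 ± 0.57. Neuronal genes differed too, with Gria1 at 4.8 ± 0.59 and Rbfox3 at 3.68 ± 0.51, and so did the astrocyte gene Gjb6 at 4.35 ± 0.87. In the opposite direction were Mcam at -4.87 ± 0.58, Plxnb3, a semaphorin receptor gene, at -4.21 ± 0.52, Cnp at -3.33 ± 0.58 and Ugt8a at -2.99 ± 0.39. Egfr differed by 3.92 ± 0.83 (adjusted p = 0.019) and did not pass without Nestin control 3 (3.83) or NG2 control 3 (3.72). Sox10 differed by -3.18 ± 0.64 (adjusted p = 0.0153) and did not pass without NG2 control 3 (-3.14). Cspg4 (-1.37), Nes (0.24), Nf1 (-0.63), Olig2 (-0.77), Pdgfra (-1.0), Gfap (1.79), Dcx (3.57) and Erbb3 (-1.61) did not pass. Of these Erbb3 passed without NG2 tumor 1 (-1.76), NG2 tumor 2 (-1.81) or NG2 tumor 3 (-1.28), Dcx without NG2 tumor 2 (4.13) or NG2 tumor 4 (2.78), and Gfap without NG2 tumor 1 (2.30). With the slide as a block the difference was 3.73 for Egfr (adjusted p = 0.0864), 4.29 for Gjb6 (adjusted p = 0.0588), -3.14 for Sox10 (adjusted p = 0.021) and 3.86 for Rbfox3 (adjusted p = 0.00523).

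Of the lists, 6 of 12 neuroblast genes had a higher Nestin effect, 10 adjusted over the list alone (mean 2.39, adjusted p = 9.51e-10). So had 4 of 16 neuron genes, 7 adjusted over the list alone (mean 1.61, adjusted p = 1.96e-06). The same held for 3 of 15 astrocyte genes, with 8 rises and 1 fall adjusted over the list alone (mean 1.43, adjusted p = 0.000322), and 2 of 12 receptor genes, 3 adjusted over the list alone (mean 1.11, adjusted p = 0.0101). The Nestin effect was lower for 4 of 15 myelin genes, with 1 rise and 4 falls adjusted over the list alone (mean -1.01, adjusted p = 0.00353), and for 2 of 20 oligodendrocyte progenitor genes, 5 adjusted over the list alone (mean -0.81, adjusted p = 0.0139). It was lower for 0 of 15 mitosis genes, 4 adjusted over the list alone (mean -0.58, adjusted p = 0.00395), and for 2 of 20 replication genes, 3 adjusted over the list alone (mean -0.50, adjusted p = 0.0055). Of the vascular lists it was lower for 0 of 16 endothelium genes (mean -0.55, adjusted p = 0.0165) and 1 of 9 pericyte genes (mean -0.76, adjusted p = 0.0233). None of these 10 calls held with an estimated correlation, where the values ran from adjusted p = 0.131 to 0.506. The myelin list had a mean of -0.03 between tumors and 0.97 between controls, so the mean of its difference of effects rests on the controls. This does not hold for each gene, since 2 of its 15 genes were higher and 3 lower in Nestin than in NG2 tumors. For the neuroblast list the means were 0.70 between tumors and -1.69 between controls, so most of its mean difference rests on the controls too. All 10 passed again with the slide as a block, and so did the meninges (mean 1.08) and choroid plexus lists (mean 1.93, adjusted p = 0.047 for both), which did not pass without it. The endothelium call was lost without Nestin tumor 1 (mean -0.36) and the pericyte call without NG2 tumor 4 (-0.59), Nestin tumor 3 (-0.67) or NG2 control 2 (-0.74). The microglia list (mean 0.63, adjusted p = 0.0559) passed without Nestin tumor 1 or 3, NG2 tumor 1 or 3, Nestin control 3, or NG2 control 1 or 3 (means 0.64 to 0.97). The meninges list (mean 1.06) passed without Nestin tumor 1, NG2 tumor 3, Nestin control 3 or NG2 control 3 (1.08 to 1.56), and the choroid plexus list (mean 2.06) without Nestin tumor 1 or 2 or NG2 tumor 3 (2.40 to 3.08). The choroid plexus list had a mean of only 0.23 without Nestin tumor 3. The hypoxia list (mean -0.45) passed without NG2 tumor 2 or 3 or Nestin tumor 3 (-0.69 to -0.59), and the classical list (mean 0.73) without Nestin tumor 1 or any 1 Nestin control (0.84 to 0.93). The MAPK output list passed without Nestin tumor 1 (-0.47), the ependyma list without Nestin tumor 1 (1.46) and the striatum list without NG2 control 1 (1.10).

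The difference of effects was past the threshold for 462 genes, 299 with a higher and 163 with a lower Nestin effect. A slide block left 190, 189 of them shared. The difference of the effects measured within slides 1 and 2 alone was past the threshold for 70 genes, 67 of them shared. The count was 258, 229 and 223 without Nestin control 1, 2 or 3, 228 and 192 without NG2 control 2 or 3, and 638 at most, without NG2 tumor 2. Comparisons that use the same arrays share their chance values. The direct tumor difference and the difference of effects shared 239 genes (163 higher and 76 lower, against 16.55 and 5.63 for independent lists). Their covariance across genes was 0.442, against 0.12 in 100 simulations with no effect. At most 1 gene was shared in these, a count kept low because no effect was put in. The control difference and the difference of effects shared 196 genes in opposite directions and 0 in the same direction (covariance -0.276, against -0.137 in the simulations). The correlations were 0.758 for the first pair, against 0.683 simulated, and -0.587 for the second, weaker than the -0.731 simulated, so neither overlap is read as a shared effect. The direct tumor difference and the control difference, which share no arrays, had 22 genes higher in both (11.4 for independent lists), 10 lower in both (7.36) and 19 in opposite directions. They too use the same estimate of the spread of a gene, so the counts for independent lists are only a reference.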

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

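The tests of the slide, of olfactory bulb tissue, of melanocytes and of Schwann cells were chosen only after the results were seen, and the tests of normal brain and of other splits of the arrays were set beforehand. The difference of the tumor effects drew attention to 462 genes, as a test of the difference itself. Among the genes named, a higher Nestin effect was found for Calb2 (7.15 log2), S100a5 (6.06), Doc2g (5.36), Th (5.32), Scgn (5.14), Omp (5.06), Gria1 (4.8), Col26a1 (4.35), Gjb6 (4.35), Gad2 (4.32), Slc32a1 (4.17), Egfr (3.92), Rbfox3 (3.68), Gad1 (3.41), Sp8 (3.34), Ddn (3.22), Dlx2 (2.71) and Sp9 (2.34). A lower Nestin effect was found for Mcam (-4.87), Dhh (-4.55), Plxnb3 (-4.21), Gata6 (-3.68), Cd6 (-3.47), Cnp (-3.33), Trbv13-2 (-3.26), Sox10 (-3.18) and Ugt8a (-2.99). Some of these calls were lost on leaving out 1 array, Egfr without Nestin control 3 (3.83) or NG2 control 3 (3.72) and Sox10 without NG2 control 3 (-3.14). Dhh was lost without Nestin tumor 1 or 3, NG2 tumor 4 or any 1 of the 6 controls (-4.73 to -4.11) and Gata6 without any 1 of the arrays but NG2 tumor 1 (-4.01 to -3.20). The lists with a different effect were neuroblast (2.39), neuron (1.61), astrocyte (1.43), glutamate and GABA receptor (1.11), myelin (-1.01), oligodendrocyte progenitor (-0.81), pericyte (-0.76), mitosis (-0.58), endothelium (-0.55) and DNA replication (-0.50), and none of these 10 calls held with an estimated correlation (adjusted p = 0.131 to 0.506). The endothelium call was lost without Nestin tumor 1 (-0.36) and the pericyte call without NG2 tumor 4 (-0.59), Nestin tumor 3 (-0.67) or NG2 control 2 (-0.74). The mean of the myelin list rests on the controls (-0.03 between tumors and 0.97 between controls), and so does most of the neuroblast mean (0.70 and -1.69). Single myelin genes also differed between tumors, 2 higher and 3 lower in Nestin tumors. Probes with no gene name, which enter no comparison by gene, passed as well: 1954 of 5028 in Nestin tumors, 2193 in NG2 tumors, 271 between tumors, 123 between controls and 119 in the difference of effects.

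Single NG2 tumors lay far from the other 3, with a ratio of the gap to the range above Dixon's critical value for 4 arrays. They were NG2 tumor 1 for Hoxc9 (0.983), Dlx2 (0.922), Hoxa2 (0.917), Slc17a6 (0.914), Mcam (0.911), Hoxd8 (0.906) and Cd44 (0.833), NG2 tumor 2 for the p53 target list (0.908), NG2 tumor 3 for the classical subtype list (0.896) and Ttr (0.878) and NG2 tumor 4 for Ccl5 (0.893). These were 11 of 145 values tested, and chance puts about 1 in 20 groups past the critical value. The values tested included those of genes named here, and the Hox genes and Ttr were picked after their values were seen. The count of 11 is therefore not read as an excess over chance.

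The first pattern weighed is the set of 1072 genes that differed between Nestin and NG2 tumors. Of the 660 genes higher in Nestin tumors 152 lay above both control groups and passed against Nestin controls (23%, just over the bound of 20% set beforehand). More normal brain of the kind in the control pieces cannot account for these 152. Normal tissue of another kind, which could lie above both control groups, was not tested and stays open. Of 543 genes at least 4-fold lower in both models than in controls 485 (89.3%) were higher in Nestin tumors, 172 of them past the threshold, so for these genes normal brain stays open, as does a biological difference between the models. A slide effect as the cause of the whole set is argued against by the difference of effects measured within slides 1 and 2, with a median of 1.26 log2 in the direction of the tumor difference (5th percentile 0.26, 97.2% in that direction) against a median tumor difference of 1.31, on genes chosen with the same arrays. Under a slide block the median tumor difference was 1.40 (5th to 95th percentile 0.47 to 3.33) against 1.31 (0.73 to 2.99), and the calls ended because the median standard error rose from 0.262 to 0.543.

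The second pattern is the set of 419 genes that differed between the controls. Under a slide block 83 passed again in the same direction, which argues against the slide as their cause. All 419 were chosen with the same arrays, so agreement in direction is partly built in. For the other 336 the median difference was 1.39 log2 with the block (5th to 95th percentile 0.70 to 3.07, all in the same direction) against 1.35 without it, and these calls ended because the median standard error of all genes rose from 0.28 to 0.451. Of 12 measured olfactory bulb genes that stood on no fixed list 6 were lower in Nestin controls (mean -2.12). Of the 17 genes listed 15 were measured, and 3 of them stand on other lists. The bulb genes were chosen after the results were seen and come from the same arrays, so they are not a separate test. Omp was at 12.03 log2 in NG2 controls, so a candidate explanation is that the NG2 control pieces held bulb tissue and the Nestin control pieces did not. Whether the strain or the anatomical position of the controls differed was not tested.

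The third pattern is the higher level of Dhh, Dct, Pmel, Mcam and Gata6 in NG2 tumors. Melanocytes or Schwann cells in the pieces could be the source, and neither can be told apart from expression by the tumor cells. Of 3 further melanocyte genes that were dim in Nestin tumors 0 were at least 4-fold higher in NG2 tumors, but none of the 3 reached 7 log2 in any group (highest 5.79), so they exclude nothing. Of 5 further Schwann cell genes that were dim in Nestin tumors 3 were at least 4-fold higher in NG2 tumors (highest group mean 8.38). None of these 3 passed between tumors (adjusted p = 0.054 to 0.103), and taking only dim genes left out a Schwann cell gene that was higher in Nestin tumors by 1.90 (adjusted p = 0.0846), so this count supports nothing either. An earlier form of both tests, the count of such genes past the threshold between tumors in the predicted direction (0 of 6 and 0 of 7, with 1 melanocyte gene past it in the opposite direction at 1.40, adjusted p = 0.00255), was replaced after it was seen, because a missed threshold excludes nothing.

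Other splits of the same arrays into groups of the same sizes were fitted in the same way. For NG2 tumor against control 1 of 35 splits, the real one, reached 6041 genes. The highest other, with NG2 tumor 2 among the controls, gave 3249. The same held for the tumor groups (1 of 35, 1072 against 538) and the difference of effects (1 of 100 drawn, 462 against 177). These shares lie under 5%, but 1 of 35 is the lowest that those splits can give. They make chance unlikely and do not exclude it. Splits that mix tumors with controls also put the difference between them into the spread, which lowers their counts. The split with 538 set NG2 tumors 1, 3 and 4, all on slide 2, against the rest. The real tumor split also set slide 2 against slides 1 and 3, and 0 genes passed with the slide as a block, so these splits do not tell the models from the slides. For the Nestin comparison (5522 against 0) and the controls (419 against 5) the 10 splits are too few for a share under 5%. For lists at the preset correlation some other splits gave as many or more. With the real split counted in, 4 of 10 splits reached the real count for the Nestin comparison (17 lists, highest other 18). The share was 5 of 35 for the NG2 comparison (17, 20) and 3 of 35 between tumors (14, 18). It was 5 of 10 between controls (4, 6) and 35 of 100 for the difference of effects (10, 17). The number of lists past the threshold is therefore not told apart from that of other splits, for the comparisons with enough splits to tell.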

How the results depend on the processing

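Leaving out slide 3 and the block for sex were chosen only after the data were seen, and all other alternatives were set beforehand. Of 20548 values of single genes over the alternatives 19462 stayed on their side of the threshold, with the same direction where they were past it, 821 were no longer past it, 264 came past it and 1 came past it in the other direction. For lists 4254 of 4451 stayed, 111 were no longer past it, 85 came past it and 1 lost its call as its test turned, and 274 of 313 counts stayed within 1.5 times. The gene was Alas2 in Nestin tumors, at 0.16 with all arrays, -1.52 without Nestin tumor 1 and up to 1.04 without others. The list was the microglia list between tumors, at 0.53 with all arrays, 0.04 without Nestin tumor 2, and up to 0.87 without others. Signal over background limits dim genes, and no filter on them gave 781 genes between tumors and 361 for the difference of effects. In what follows the cause was not tested unless it is stated.

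Taking every probe on its own gave 10287, 11576, 1678, 755 and 775 probes in the order of the comparisons, since more items were tested. Between tumors 1072 genes passed, 61.6% of them higher in Nestin tumors. The count was 707 with the replicate number as a block and 0 with the slide as a block. With only the tumors in the fit it was 167 (79% higher). It was 383 at an adjusted p below 0.01 (72.3% higher, a stricter threshold) and 311 without slide 3 (fewer arrays). The fit of the tumors alone left the controls out of the shared spread. The median SD of a gene was larger in tumors (0.3 and 0.347 log2) than in controls (0.221 and 0.274). The replicate block gave 5552, 5601, 357 and 310 in the other comparisons, and changed no other count by more than 1.5 times. Arrays with the same number did not deviate together (median correlation -0.0055 over 18 pairs, -0.161 to 0.13), so the number was not read as a pairing, and a block by the title letter gave 794 between tumors. For the controls the count of 419 became 830 with array weights, 87 with the slide as a block (28.7% higher in Nestin controls, against 49.2%), 952 with only the controls in the fit, 216 at 0.01 and 71 without slide 3. For the difference of effects 462 became 829 with array weights, 190 with the slide as a block, 131 at 0.01 and 43 without slide 3. Leaving out 1 array gave 663 to 1248 between tumors, 189 to 457 between controls and 192 to 638 for the difference of effects. A group left with 2 arrays was assumed to vary like the others.

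At the preset correlation 17, 17, 14, 4 and 10 lists passed. With an estimated correlation camera passed 1, 1, 0, 2 and 0, and the counts of 0 stand beside 3 lists between tumors and 2 for the difference of effects at an unadjusted p below 0.05. With fry, which does not set a list against other genes, 19, 22, 11, 2 and 4 passed, and with the slide as a block 9 passed between tumors. Cyclic loess moved the share of higher values in the difference of effects from 64.7% to 73.6%.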

Other observations

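The block for sex was chosen only after the results were seen, and the Hox genes and the transcripts given by array were picked after their values were seen. Hox genes pattern the hindbrain and spinal cord in the embryo, and 11 of them were among the tested genes. In Nestin tumors 5 rose and 1 fell (Hoxc8, at least 1.29-fold), and in NG2 tumors 4 rose and 0 fell. The 4 rose in both models: Hoxa2 (at least 13.5-fold in Nestin and 6.57-fold in NG2 tumors), Hoxa4 (at least 6.03-fold, and 2.74 log2), Hoxa5 (at least 26.8-fold and 22.8-fold) and Hoxa7 (at least 41.7-fold and 8.26-fold), with limma adjusted p-values from 2.75e-07 to 0.00116. Hoxa7 was higher in Nestin than in NG2 tumors by 2.38 (adjusted p = 0.0123), and its difference of effects of 2.34 (adjusted p = 0.104) passed without NG2 tumor 1 (2.83). Hoxc9 rose at least 7.29-fold in Nestin tumors (adjusted p = 0.00484) and did not pass in NG2 tumors (adjusted p = 0.377), and its difference of effects of 2.66 (adjusted p = 0.261) passed without NG2 tumor 1 (3.6). Hoxc9 differed between the tumor groups by 2.76 (adjusted p = 0.0569), which passed without Nestin tumor 2 (3.35) or NG2 tumor 1 (3.69). Hoxc10 (0.45 in Nestin tumors) passed without Nestin tumor 2 (0.74), and Hoxa13, Hoxc4, Hoxd8 and Hoxd11 passed in neither model.

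NG2 tumor 1 had another set of Hox genes than the other 3 NG2 tumors. Its level of Hoxa2 was 5.13 log2, against 8.88 to 9.22 in the others, its level of Hoxc9 was 8.40, against 4.47 to 4.53, and its level of Hoxd8 was 8.39, against 4.47 to 4.84. Hoxa4, Hoxa5 and Hoxa7 were high in all 4 NG2 tumors, at 7.31 to 8.46, 9.12 to 11.22 and 6.84 to 9.82. Hoxc9 was at 7.01 to 9.93 and Hoxa2 at 8.94 to 9.40 in the 3 Nestin tumors.

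Ttr, the transthyretin gene and an abundant transcript of the choroid plexus, was at 14.11 log2 in Nestin tumor 3 and at most 8.0 on the other 12 arrays. The choroid plexus list differed by a mean of 4.85 between Nestin tumor 3 and the Nestin control of the same slide, and by -0.77 within slide 1. Xist, which is expressed from the inactive X chromosome, was at 9.85 in Nestin control 2, 10.40 in Nestin tumor 3, 10.13 in NG2 control 2, 11.45 in NG2 tumor 1 and 10.78 in NG2 tumor 2, and at most 4.67 on the other 8 arrays. The Y-linked gene Eif2s3y was at 7.44 or more on 7 of these 8 arrays and at 5.33 in NG2 tumor 4, the only array low in both. With a block for sex, read from Xist, the counts of genes past the threshold were 5390, 5911, 987, 372 and 425 in the order of the comparisons, against 5522, 6041, 1072, 419 and 462. The block put NG2 tumor 4 with the other arrays low in Xist, although its sex is not settled by these genes.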
